A study of Homo sapiens with 4 samples.

How the data were processed

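Messenger RNA was measured in 4 libraries of H2030, an established human lung adenocarcinoma cell line: 2 labelled control vector and 2 labelled GALNT3 overexpression. Per the labels' protocols, cells at passage 5 to 10 were grown for 2 days in RPMI with 10% serum, RNA was purified on silica columns, and libraries were made with a stranded poly(A) mRNA kit. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. No treatment is recorded.

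The authors deposited one table of 20252 gene symbols with 1 column of FPKM (fragments scaled by transcript length and by the mapped fragments of the library) per library. The file header names no unit. FPKM was read from the values: they are not whole, the columns sum to 401366 to 448194, and the value of 1 fragment shrinks as transcripts lengthen. The submitters' processing notes list TopHat, GenomeStudio 2010.1 and the builds GRCh38 and hg19, with no roles. The counting program, annotation and filters are not given in the sources used here. Because FPKM divides by each library's total, a few abundant genes can move all other values of a library, and overlapping genes or near-identical paralogs can exchange fragments. No column of per-sample values was left unassigned.

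The row order was checked. Of the 20252 rows, 2615 were out of alphabetical order. They were almost all rows with a large difference between the groups: 1139 of the 1141 rows whose ratio of group means (GALNT3 overexpression over vector) was above 0 and at most 0.667, and 1340 of the 1342 rows with a ratio of at least 1.5. Only 8 of the 12689 rows with a ratio between 0.667 and 1.4 were displaced. Among the displaced rows with low ratios, position followed the ratio exactly (Spearman's rho = -1.0 across rows). Whether symbols and values were still joined was tested on genes below 0.2 FPKM, where the lowest value should fall with transcript length. Spearman's rho was -0.54 across 1508 displaced rows and -0.39 across 1365 rows in order, while the lowest of 1000 shuffles of the displaced rows was -0.08. Rows are not independent replicates.

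Whole fragments were visible as steps in the low values. The ratio of these steps between libraries gave relative depths of 1.07 and 0.988 for vector replicates 1 and 2, and 0.973 and 0.966 for GALNT3 overexpression replicates 1 and 2, relative to their mean. The total number of reads per library is unknown. Intervals made from these fragments cover counting error only. An exact 0 can be a failed estimate: RPL21, one of 109 ribosomal protein and housekeeping genes looked up, was listed at 0 in 2 libraries and at 70.7 and 123.6 FPKM in the other two. Genes listed at 0 are therefore given per library.

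Genes with a mean of at least 1 FPKM over the 4 libraries were tested (10998 genes). Values were transformed to log2(FPKM + 1), a scale that understates changes of low genes, and compared with limma 3.58.1 (lmFit and eBayes with a mean-variance trend) in R 4.3.3, with group as the only term. P-values are two-sided and adjusted by the Benjamini-Hochberg method, and the threshold was 0.05. With 2 libraries against 2, an exact permutation test of one gene cannot go below p = 0.333, so all calls rest on limma's sharing of variance between genes, with 2 residual and 5.34 prior degrees of freedom. Means are given ± SD of 2 libraries and log2 fold changes ± SE. Every fold change is the libraries labelled GALNT3 overexpression relative to those labelled vector.

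Before the data were examined, 41 gene lists were fixed: glycosylation, mucins, cytokines, signalling targets, metabolism, cell cycle, epithelial and mesenchymal genes, lineage and cell type markers, and RNA quality. Older symbols were matched through RefSeq and GENCODE 29 names: 18079 symbols are current, 1932 matched through an older name and 241 did not match. The 34 lists with at least 5 tested members were compared with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. The calls were repeated with an estimated correlation and with fry. Mitochondrially encoded genes were not analysed here.

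Genes named in the text followed a rule fixed at the same time. The rule takes GALNT3, then up to 8 genes per direction with the largest change among called genes whose mean log2 value was at or above the median of tested genes (3.54), with a current symbol and no overlap between groups. It then takes up to 4 genes with the smallest adjusted p from each called list and from each list tied to the study. Genes listed at 0, and single members named beside a count for other lists, were chosen after their values were seen. Positions are from GENCODE 29 on GRCh38, matched by symbol, since the deposited table holds no coordinates.

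Python 3.11.15 with scipy 1.17.1 was used for the checks of the file. The procedure was tested on simulated data for this comparison: 10998 genes with 200 changed. It called 54.4% of genes changed 1.5-fold, 92.4% of those changed 2-fold and 100% of those changed 4-fold, and 3.53% of calls were unchanged genes. With no change it called 0 genes and 0 lists. Genes were simulated as independent of each other and without replicate effects, so this does not test false list calls among correlated members. In the data the estimated correlation of the 5 lists called below ran from -0.067 (histone genes) to 0.90 (ribosomal protein genes), against the preset 0.01. Alternatives tried were median centring, quantile normalization, other filters and pseudocounts, limma without a trend, a replicate block, each library left out, a minimum change of 1.5-fold, a threshold of 0.01 and, chosen after seeing the data, leaving out genes listed at 0 and fry.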

Results

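Poly(A) RNA profiles were obtained from H2030 lung adenocarcinoma cells, with 2 libraries labelled control vector and 2 labelled GALNT3 overexpression. GALNT3 encodes a Golgi enzyme that starts mucin-type O-glycosylation by adding N-acetylgalactosamine to serine or threonine. The comparison asks which transcripts differ between the libraries carrying these labels. Between 14705 and 14891 genes were above 0 in a library, and between 10915 and 11073 reached 1 FPKM. Relative depth ranged from 0.966 to 1.07. Across genes, log2(FPKM + 1) correlated at r = 0.990 between the vector libraries and r = 0.990 between the GALNT3 overexpression libraries, against 0.987 to 0.989 between groups. Genes are not independent replicates in these correlations.

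GALNT3 itself was measured at the opposite of its label. It stood at 4.34 and 5.34 FPKM in the libraries labelled vector, and at 0.0164 and 0 FPKM in the libraries labelled GALNT3 overexpression. Taking 0.0164 FPKM as 1 fragment, the values came out as 291 and 330 fragments in vector replicates 1 and 2, each within 0.001 of a whole number. That is 621 fragments against 1, a depth-corrected ratio of 584 (95% exact interval 104 to 23107, counting error only). On the log2(FPKM + 1) scale the difference was -2.53 ± 0.13 (SE; limma, adjusted p = 3.78e-04). The gene lies on the minus strand of chromosome 2, from 165747591 to 165794682 (GRCh38). Directions below are therefore given between the libraries as labelled, and all of them would turn if the labels of the groups were exchanged.

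The other GALNT genes, which encode enzymes of the same family, did not pass the test. Of 8 tested members 0 passed in limma, also when adjusted over the list alone, and 1, GALNT14, had an unadjusted p below 0.05. GALNT14 was at 33.6 ± 1.0 FPKM in the libraries labelled vector and 39.2 ± 0.69 in those labelled GALNT3 overexpression (SD, n = 2; adjusted p = 0.605). GALNT2, the most abundant, was at 51.0 ± 0.36 and 44.8 ± 4.3 FPKM (adjusted p = 0.769). GALNT7 was at 10.9 and 9.68 FPKM, and GALNT4 at 1.68 and 1.30. Of 11 tested genes in the list of O-glycan core and sialylation enzymes, which also holds enzymes of N-glycans such as FUT8, 0 passed, with GCNT3, FUT8, ST3GAL4 and B4GALT1 at adjusted p of 0.444, 0.631, 0.770 and 0.858, and 2 had an unadjusted p below 0.05. The tested mucins, MUC1 and CD164, were at 11.5 against 12.5 FPKM and at 53.3 against 49.8 FPKM, and 0 passed, adjusted or unadjusted.

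**Figure D1:**
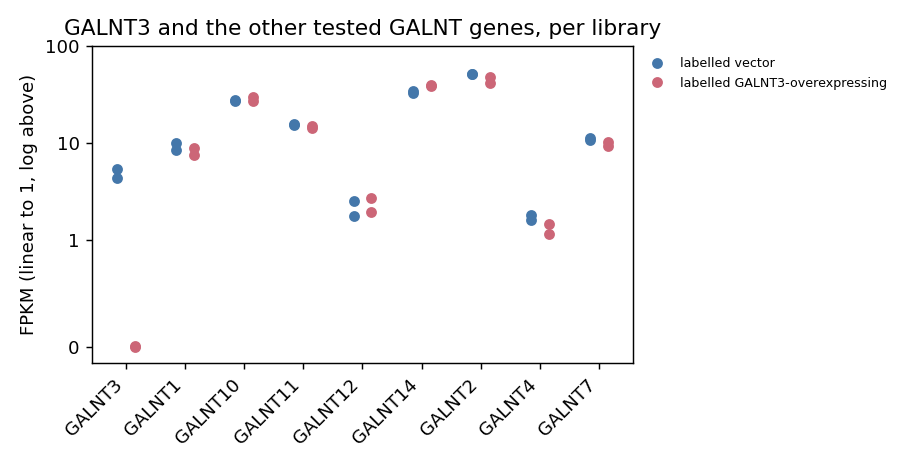
FPKM of GALNT3 and the 8 other tested GALNT genes (vertical axis, linear to 1 and logarithmic above), with 1 point per library, blue for libraries labelled vector and red for those labelled GALNT3 overexpression. GALNT3 stands at 4.34 and 5.34 in the blue libraries and at 0.0164 and 0 in the red ones, while the other genes lie close together in both groups.

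Across the transcriptome, 55 of 10998 tested genes passed the threshold: 12 were higher and 43 lower in the libraries labelled GALNT3 overexpression. Of these, 33 changed by at least 1 on the log2 scale. Over all tested genes, passing or not, both libraries labelled GALNT3 overexpression lay above both others in 2297 genes and below them in 1683, together 36.2% of genes against 33.3% by chance. The highest-ranked rise among well-expressed genes was SCEL (sciellin, a protein of the cornified envelope; chromosome 13, 77535674 to 77645263), from 9.06 ± 0.66 to 24.9 ± 1.0 FPKM (SD, n = 2), a log2 change of 1.36 ± 0.10 (SE; limma, adjusted p = 0.00182). SLPI, a secreted inhibitor of leukocyte proteases, rose from 26.6 ± 5.0 to 55.7 ± 5.3 FPKM. JAG2, a Notch ligand, rose from 7.35 ± 0.27 to 15.4 ± 1.6 FPKM, and IL13RA2, a decoy receptor for interleukin 13, from 11.5 ± 0.67 to 22.1 ± 1.1 FPKM. The lung-enriched transcript SFTA1P, the integrin activator FERMT1 (kindlin-1) and FAM110C rose 1.75-fold, 1.70-fold and 1.64-fold. The adjusted p of these 6 genes (limma) ranged from 0.0128 for JAG2 to 0.0462 for FAM110C.

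Among well-expressed genes that were lower, AKR1C1, a steroid and carbonyl reductase, fell from 63.9 ± 26 to 19.5 ± 2.6 FPKM (SD, n = 2), a log2 change of -1.61 ± 0.24 (SE; limma, adjusted p = 0.0499). It has near-identical paralogs, so its level is uncertain, and its change was -1.19 without vector replicate 1, where it did not pass (0.0593). HTATIP2 fell from 17.8 ± 1.7 to 6.66 ± 0.55 FPKM (chromosome 11, 20363685 to 20383783; adjusted p = 0.00500). TGM2, the tissue transglutaminase that crosslinks proteins, fell from 106 ± 8.1 to 49.6 ± 2.9 FPKM (chromosome 20, 38127387 to 38166578; adjusted p = 0.00500). SEC22C, a protein of vesicle transport between the endoplasmic reticulum and the Golgi, fell from 17.4 ± 1.3 to 7.72 ± 0.18 FPKM. EPAS1, which encodes the hypoxia-inducible factor HIF-2 alpha, fell from 18.6 ± 3.2 to 8.87 ± 0.56 FPKM, and the carboxypeptidase CPA4 from 19.9 ± 1.6 to 9.96 ± 0.87 FPKM. The noncoding RNA RMRP was at 22.5 ± 0.34 and 9.78 ± 2.5 FPKM (limma, adjusted p = 0.0284). It did not pass with median centring (0.0628) or quantile normalization (0.0765). HLA-B, a class I antigen-presenting molecule with close paralogs, fell from 49.1 ± 3.6 to 29.1 ± 1.8 FPKM (adjusted p = 0.0269).

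**Figure D2:**
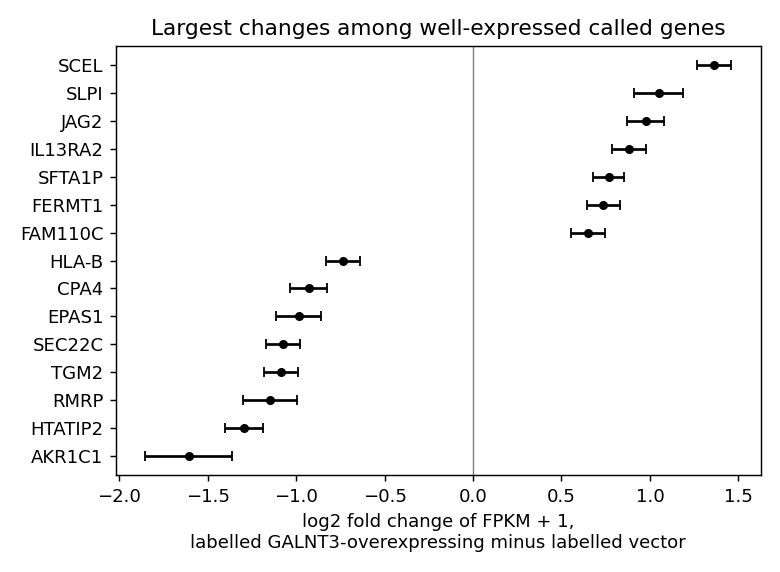
Log2 fold change of FPKM + 1, labelled GALNT3 overexpression minus labelled vector (horizontal axis), for the 15 well-expressed genes named by the rule; points are limma estimates and bars their standard errors. The 7 higher genes run from 0.65 for FAM110C to 1.36 for SCEL, and the 8 lower genes from -0.74 for HLA-B to -1.61 for AKR1C1.

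The number of calls depended on single libraries. It was 23 without vector replicate 1 (15 of the 55 remained), 42 without vector replicate 2 (29 remained), 79 without GALNT3 overexpression replicate 1 and 83 without GALNT3 overexpression replicate 2. Of the 15 well-expressed genes only SCEL and HTATIP2 passed with each library left out. Of the 55 calls, 9 were listed at exactly 0 in both libraries of one group. The smallest p-values of all were among these: RWDD3 was listed at 11.2 and 10.3 FPKM in the libraries labelled vector and at 0 in both others, and HYI at 0 in both libraries labelled vector and at 9.33 and 10.2 FPKM in the others. Testing every gene above 0 in any library (15991 genes) left 12 calls, among which none of the 15 well-expressed genes remained.

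Of the 11 tested chemokines and cytokines that draw myeloid cells, 0 passed over all genes. Adjusted over the list alone 3 passed: CXCL1 and S100A9 higher and CCL2 lower. CXCL1, a neutrophil chemokine, was at 9.96 ± 2.1 and 15.2 ± 2.0 FPKM in the libraries labelled vector and GALNT3 overexpression (SD, n = 2; adjusted p over all genes 0.315). S100A9, a calcium-binding protein that attracts myeloid cells, was at 6.02 ± 2.5 and 13.0 ± 4.3 FPKM (0.322). CCL2, the monocyte chemokine, was at 363 ± 87 and 206 ± 64 FPKM (0.352), and IL6 at 41.7 ± 0.77 and 35.2 ± 0.88 FPKM (0.551). Without GALNT3 overexpression replicate 2, S100A9 (0.0256) and CCL2 (0.0288) passed over all genes. The list as a whole did not pass (camera, adjusted p = 0.385). Its medians, relative to the mean of the 4 libraries, followed replicate number. They were -0.032 (vector) and -0.095 (GALNT3 overexpression) in replicate 1, and 0.12 and 0.15 in replicate 2. Leaving out 1 library unbalances the replicate numbers, so list calls in those fits cannot be told apart from a difference between replicate numbers.

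Of 33 tested target genes of TNF and NF-kB, 1 fell over all genes: TNFAIP2, from 4.29 ± 0.49 to 1.26 ± 0.24 FPKM (SD, n = 2; limma, adjusted p = 0.0128). Over the list alone PLAUR, the urokinase receptor (43.5 ± 0.80 and 57.4 ± 1.2 FPKM, higher), and IL32 (2.72 ± 0.66 and 1.29 ± 0.15 FPKM, lower) also passed. The list did not pass (camera, adjusted p = 0.652). Its medians, relative to the mean of the 4 libraries, also followed replicate number. They were -0.039 (vector) and -0.095 (GALNT3 overexpression) in replicate 1, and 0.077 and 0.063 in replicate 2. List calls with 1 library left out therefore cannot be told apart from a difference between replicate numbers. Of 18 tested TNF receptors and their signalling partners, 1 fell: LTBR, the lymphotoxin beta receptor, from 7.24 ± 0.32 to 2.73 ± 0.41 FPKM (adjusted p = 0.0111). The TNF receptor list had a camera adjusted p of 0.944. Without vector replicate 1, TNFAIP2 and LTBR each had an adjusted p of 0.0949, and without vector replicate 2 LTBR had 0.0567. With every gene above 0 tested, TNFAIP2 and LTBR each had 0.152.

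Of 23 tested angiogenesis factors 0 passed over all genes and 4 passed over the list alone (limma). Lower among these were ANG (angiogenin; 7.34 ± 2.6 and 3.42 ± 0.039 FPKM) and EDN1 (endothelin 1; 3.36 ± 0.16 and 2.07 ± 0.12 FPKM), and higher were PLAUR and EFNA1 (56.2 ± 9.5 and 81.0 ± 3.9 FPKM). Without vector replicate 2, ANG passed over all genes (adjusted p = 0.0312). Of 22 genes of MET, EGFR and other receptor tyrosine kinases 0 passed over all genes or over the list alone, and 4 had an unadjusted p below 0.05. Of 19 targets of Wnt and beta-catenin 0 passed by either adjustment and 2 had an unadjusted p below 0.05. Of 11 self-renewal genes 1, CD44, passed over the list alone, at 32.2 ± 3.0 and 22.1 ± 3.3 FPKM (adjusted p over all genes 0.219). The camera adjusted p of these 4 lists was 0.632, 0.605, 0.944 and 0.791.

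Of 19 epithelial genes tested, 0 passed over all genes and 8 passed over the list alone (limma), 4 higher and 4 lower, with camera adjusted p = 0.654. KRT7, a keratin of simple epithelia, was at 7.34 ± 0.22 and 4.71 ± 0.67 FPKM, and LAMB3, a laminin chain, at 9.25 ± 2.4 and 4.06 ± 1.4 FPKM. PKP2, a desmosomal protein, was at 9.33 ± 1.4 and 13.3 ± 0.29 FPKM, and LSR, a tricellular junction protein, at 66.2 ± 1.1 and 82.9 ± 0.55 FPKM (SD, n = 2). Of 19 mesenchymal genes 1, CDH11, passed over the list alone, at 10.8 ± 3.1 and 20.4 ± 4.1 FPKM, and COL3A1, TNC and TWIST1 did not pass. Without GALNT3 overexpression replicate 2, LAMB3 (0.00794) and CDH11 (0.0288) passed over all genes.

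Of the 34 lists tested, 5 passed with camera's preset correlation, and each lost its call with an estimated correlation (adjusted p = 0.983 with an estimated correlation for all 5). Genes of antigen presentation were lower: of 18 tested 1 fell over all genes (HLA-B) and 4 over the list alone, with a median log2 change of -0.17 (camera, adjusted p = 1.81e-05). The class I molecule HLA-C, which has close paralogs, was at 15.1 against 11.7 FPKM, and NLRC5, a transactivator of class I genes, at 2.53 against 1.65 FPKM. Targets of NRF2, the regulator of the antioxidant response, were lower: of 31 tested 2 fell over all genes (CBR3 and AKR1C1), 3 over the list alone, and the median log2 change was -0.07 (camera, adjusted p = 4.28e-05). CBR3 did not pass without vector replicate 1 (adjusted p = 0.124), without vector replicate 2 (0.0610) or with every gene above 0 tested (0.152). AKR1C1, close to the threshold, did not pass without vector replicate 1 (0.0593), with median centring (0.0824), quantile normalization (0.110), every gene above 0 (0.314) or a pseudocount of 5 (0.0561), or without the trend (0.0667). AKR1C3 was at 60.8 ± 18 and 26.0 ± 2.6 FPKM (SD, n = 2; limma, adjusted p = 0.0635) and GCLC, which makes the first product of glutathione synthesis, at 16.5 ± 0.20 and 13.0 ± 0.47 FPKM (adjusted p = 0.351). AKR1C3 passed with the replicate block (limma, adjusted p = 6.36e-05), with a mean of at least 5 FPKM (0.0349) and without genes listed at 0 (0.0216). Its log2 change was -1.47 without vector replicate 2, and -1.27 and -1.07 without GALNT3 overexpression replicate 1 and 2. Over all alternative fits its change ran from -1.47 to -0.86.

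Interferon-stimulated genes were lower as a list (27 tested, 0 passing alone, 3 with an unadjusted p below 0.05; median log2 change -0.12; camera, adjusted p = 0.00657). Relative to the mean of the 4 libraries, the interferon medians were 0.22 and -0.066 in vector replicates 1 and 2. In GALNT3 overexpression replicates 1 and 2 they were 0.018 and -0.12. They overlapped between the groups and followed replicate number. Losses of this call without vector replicate 1 and without GALNT3 overexpression replicate 2 cannot be told apart from a difference between replicate numbers. The call was also lost with quantile normalization (camera, adjusted p = 0.0571) and with a mean of at least 5 FPKM (0.0570). Medians did not overlap for antigen presentation (0.16 and 0.054 in vector replicates 1 and 2, -0.10 and -0.092 in the GALNT3 overexpression replicates). The same held for NRF2 targets (0.13 and -0.0091, against -0.066 and -0.072). The remaining called lists, histone and ribosomal protein genes, were markers of RNA composition. Of these only the histone medians separated the groups. Relative to the mean of the 4 libraries, the histone medians were 0.12 and 0.096 in vector replicates 1 and 2. They were -0.16 and -0.19 in GALNT3 overexpression replicates 1 and 2. The ribosomal medians overlapped between groups and followed replicate number: 0.044 and -0.16 in the vector replicates, 0.15 and -0.019 in the GALNT3 overexpression replicates. Replication-dependent histone genes, whose messages mostly lack poly(A) tails, were lower (10 tested, 0 passing over all genes and 2 over the list alone, HIST1H1C and HIST1H4H, of which HIST1H1C passed over all genes, at 0.0412, when genes listed at 0 were left out; median log2 change -0.27; camera, adjusted p = 3.24e-04). Ribosomal protein genes were higher (79 tested, 0 passing over all genes or over the list alone and 0 with an unadjusted p below 0.05; median log2 change 0.11; camera, adjusted p = 1.08e-04). RPS29 was at 2320 ± 243 FPKM in the libraries labelled vector and 2947 ± 228 FPKM in the others. The ribosomal call was lost with quantile normalization (camera, adjusted p = 0.321). It was also lost without vector replicate 2 and without GALNT3 overexpression replicate 1. Those 2 losses cannot be told apart from a difference between replicate numbers.

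**Figure D3:**
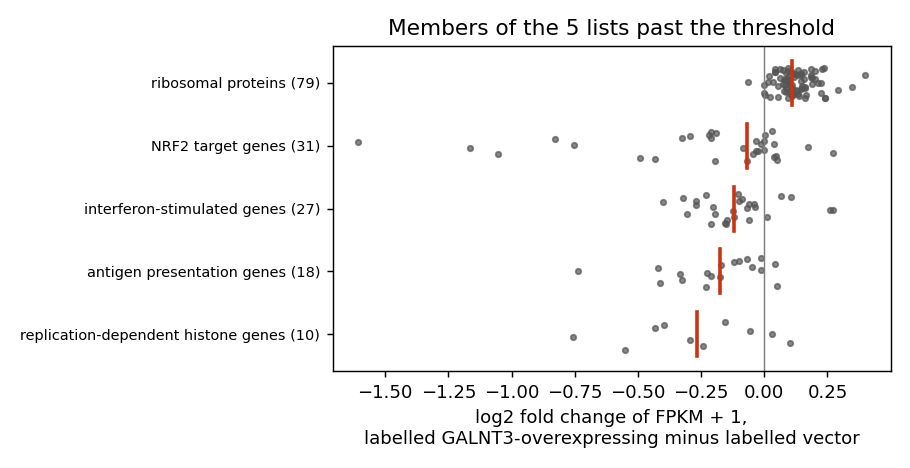
Log2 fold change of FPKM + 1, labelled GALNT3 overexpression minus labelled vector (horizontal axis), of every tested member of the 5 called lists (grey points, with the number tested in parentheses) and the list median (red bar). The medians run from -0.27 for histone genes to 0.11 for ribosomal protein genes, and the NRF2 list has its lowest point at AKR1C1, at -1.61.

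The other 29 lists had camera adjusted p from 0.138 to 0.979. In many of these lists the medians, relative to the mean of the 4 libraries, followed replicate number, upward in some and downward in others. The G2/M median was -0.082 (vector) and -0.067 (GALNT3 overexpression) in replicate 1, and 0.036 and 0.13 in replicate 2. For MYC and ribosome biogenesis genes it was -0.075 and -0.022, then 0.015 and 0.083. For YAP/TAZ targets it was -0.052 and -0.029, then 0.030 and 0.070. Fatty acid synthesis genes ran the other way, at 0.12 and 0.050, then -0.093 and -0.032. Calls of such lists with 1 library left out cannot be told apart from a difference between replicate numbers. G2/M genes passed with the replicate block (camera, adjusted p = 0.0371). They did not pass with an estimated correlation (0.983), a fit that could hardly pass any list. Among the 29, beside TNFAIP2 and LTBR in their lists, single members passed over all genes in the hypoxia list (CA12, lower, 1 of 26), the YAP/TAZ target list (ANKRD1, lower, 1 of 27) and the metalloproteinase list (ADAM12, lower, 1 of 14). ANKRD1 passed with each library left out, while CA12 (0.153 and 0.0786) and ADAM12 (0.102 and 0.0925) did not pass without vector replicate 1 or without vector replicate 2. Over the list alone 1 of 19 glycolysis genes passed (SLC16A3, lower), 2 of 27 YAP/TAZ targets, 4 of 20 integrins and laminins (2 higher and 2 lower) and 1 of 5 lung lineage genes (LAMP3, higher). In limma 0 members passed over the list alone for cholesterol and fatty acid synthesis, p53, ERK and AP-1, TGF-beta, the unfolded protein response, ATF4, Golgi transport, DNA replication, G2/M, ribosome biogenesis, and immediate early and heat shock genes; between 0 and 5 members of each had an unadjusted p below 0.05. Markers of other cell types were mostly under 1 FPKM. Of the leukocyte markers 3 were tested and CD68, a lysosomal protein, fell from 28.2 ± 1.5 to 16.7 ± 0.52 FPKM (SD, n = 2; adjusted p = 0.0238), but did not pass without vector replicate 1 (0.164) or without vector replicate 2 (0.0831). Of 1 endothelial, 4 fibroblast, 3 squamous and 4 neuroendocrine genes tested, 0 passed over all genes, and 1, 0, 1 and 2 passed over the list alone.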

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

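Leaving out genes listed at 0 and using fry were chosen after seeing the data. All signs of the 15 well-expressed genes held under each alternative run. The naming rule required no overlap between groups, so only median centring and quantile normalization could have turned a sign. The same is true of GALNT3, whose values did not overlap either. The calls of the 15 genes held with a mean of at least 5 FPKM, with a pseudocount of 0.1, with the block and without genes listed at 0. Calls were lost for 3 of the 15 under median centring, 6 under quantile normalization, 2 with a pseudocount of 5, 3 without the trend and 15 when every gene above 0 in any sample was tested. GALNT3 kept its direction and its call in each fit that tested it, with a log2 change from -5.51 (pseudocount 0.1) to -0.97 (pseudocount 5); it was too low for the filter at 5 FPKM and is listed at 0 in 1 library, so 2 fits left it out. With every gene above 0 tested, the counts were 12 genes, 3 higher and 9 lower. A mean of at least 5 FPKM gave 31 genes, 22 of them lower, from 7871 tested, a smaller set that holds 27 of the 55 calls, all 27 of which remained. Requiring a 1.5-fold change gave 9 genes (3 higher, 6 lower), and a threshold of 0.01 gave 18 (3 higher, 15 lower). Quantile normalization left 3 lists, without the interferon and ribosomal lists. With an estimated correlation 0 lists passed and with fry 0 lists passed. At unadjusted p below 0.05 these were 0 and 2, against 10 for camera with the preset correlation. The fit with an estimated correlation rests on the 2 residual degrees of freedom, so its count of 0 does not show an effect of correlation. For these shifts the cause was not tested. Leaving out 1 library gave 23 to 83 genes (8 to 22 higher, 14 to 62 lower), a GALNT3 log2 change of -2.65 to -2.40 and 6 to 7 lists, where the lone library is assumed to vary like the others. Among 60 other named genes, calls were gained by 30 under the replicate block, by 5 without GALNT3 overexpression replicate 2 and by at most 2 in any other fit, and the signs of B4GALT1, CD164 and MUC1, none of which had passed, turned when 1 library was left out: B4GALT1 ranged from -0.0077 to 0.34, CD164 from -0.22 to 0.021 and MUC1 from -0.19 to 0.36. The replicate numbers are shared by the groups, but the labels do not say that they pair the libraries. Deviations of same-numbered libraries correlated at 0.218 across genes, and the replicate block raised the count to 443 genes (222 higher, 221 lower), which included all 55, and to 6 lists. Low genes limit precision: below 1 FPKM they were not tested.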

Other observations

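The tests of transcript length, of the GALNT3 fragment ratio, of the side on which each library lies, of genes listed at 0 and of the lowest ribosomal median were chosen only after the result was seen. The genes in this paragraph were also chosen after their values were seen. Further genes passing the test (limma, adjusted p under 0.05) were lower in the libraries labelled GALNT3 overexpression: MCAM, a cell adhesion molecule, was at 7.56 and 5.81 FPKM in the libraries labelled vector and at 1.63 and 1.36 in the others, and VAMP8, a SNARE protein of vesicle fusion, at 13.1 and 11.7 against 4.77 and 5.16. The long noncoding RNA NEAT1 fell from 144 ± 0.95 to 93.9 ± 2.4 FPKM (SD, n = 2), and OCIAD2 from 27.3 ± 0.26 to 17.8 ± 0.19 FPKM. The growth factor MDK and the actin crosslinker FLNC had log2 changes of -1.13 and -1.21. CKB, a creatine kinase, rose from 6.60 ± 0.66 to 13.8 ± 0.73 FPKM, and SLAIN1, a microtubule-binding protein, was at 2.08 and 2.13 against 6.79 and 4.80 FPKM. Of these 8 genes, MCAM passed with each library left out. NEAT1 (adjusted p from 0.0993 to 0.201) and OCIAD2 (0.0802 to 0.210) lost the call whichever library was left out. Without vector replicate 1, VAMP8 (0.0593), FLNC (0.0600), MDK (0.124), CKB (0.0593) and SLAIN1 (0.184) did not pass, and without vector replicate 2, CKB (0.0803) and SLAIN1 (0.165) did not pass.

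GALNT3 was lower where the label says that it was overexpressed. If the sorting of rows had separated symbols from values, the value of 1 fragment would not follow transcript length in the displaced rows, but Spearman's rho there was -0.54 across low genes, below the lowest of 1000 shuffles (-0.08). This bears on the displaced rows as a set, not on a single row. Construct transcripts that the counting missed would leave the chromosomal gene at about the same level in both groups, while the lower bound of the ratio was 104, although overexpression from an uncounted construct beside a loss of the chromosomal transcripts was not tested and stays open. An exchange of the labels of the groups cannot be told apart from cells that lost GALNT3: that 4 of 4 libraries lie on the other group's side restates the pattern, and nothing else known in advance separates the groups.

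In 12 genes both libraries of one group were listed at 0 and both others at 1 FPKM or more, 9 of them at 0 in the libraries labelled GALNT3 overexpression. Failed estimates may account for part of this, since 17 genes were at 0 in 1 library of each group with the others at 1 FPKM or more. These 17 were summed over every pairing of 1 library from each group, which are more pairings than those behind the 12 genes. The counts 17 and 12 are therefore not directly comparable. Fragments assigned to an overlapping gene may also do so: 83.3% of the 12 genes overlap another protein-coding gene, against 36.3% of 2000 random tested genes (Fisher's exact test, two-sided, p = 0.00121). ENOSF1, which overlaps TYMS, was at 7.43 and 7.03 FPKM in the libraries labelled vector and listed at 0 in both others. A change in expression of these genes was not excluded.

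Ribosomal protein genes had a median log2 change of 0.11, but their medians per library overlapped between the groups. Whether single libraries carry it cannot be told. These medians also followed replicate number, and leaving out 1 library unbalances the replicate numbers. The median change was 0.02 (0.0171) without vector replicate 2 and 0.03 without GALNT3 overexpression replicate 1, against 0.22 and 0.20 without the other replicates. A scaling of abundant transcripts as a class may contribute, since the 400 most abundant other genes had a median of 0.09 (0.0909). Quantile normalization left 0.01 for the ribosomal genes. A difference between the lines named in the design stays open and was not tested apart from these.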
